A study of Halothece sp. PCC 7418 with 7 samples.

How the data were processed

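Total RNA was sequenced from 7 cultures of the halotolerant cyanobacterium Halothece sp. PCC 7418, 1 library per condition. Per the labels, a culture at 0 h served as control for the salt upshock, and another culture at 0 h served as control for nutrient starvation and sucrose. The other 5 cultures were sampled at 24 h. The authors deposited raw read counts per locus tag, as the file headers and the whole-number values show. Reads were aligned with Bowtie, per the submitters' processing notes. Its version, the counting tool, the genome build, the annotation and the strandedness of the libraries are not given in the sources used here. Reads of overlapping or near-identical genes could therefore not be told apart.

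The table holds the salt libraries and the starvation and sucrose libraries in 2 separate blocks, each with its own list of tags, 3746 in the salt block and 3689 in the other. The lowest read count in the mapped columns was 1 and none of the values was 0. Tags with no read in some library of a block therefore appear to have been left out of it, so that a gene silent in 1 condition can be missing altogether. The 2 blocks shared 3650 tags, and 96 tags stood in the salt block alone and 39 in the other block alone. The starvation and sucrose block held a further 59 rows with no tag. They took 14.2% of the reads of the control, 10.8% under N starvation, 12.7% under P starvation, 31.2% under S starvation and 7.24% under sucrose, nearly all of it in 1 row, and were left out of library sizes and comparisons. A further 2 columns of read counts match no sample described here and were not used.

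The table gives tags without gene names or products, and no annotation was used here. The 35 gene lists fixed beforehand (glycine betaine and mycosporine-2-glycine synthesis, nitrogen, phosphate and sulfur genes, photosynthesis and others) could therefore not be formed, and their medians were not computed. Tags are reported as the file gives them, without a function. Coordinates are not reported for the same reason.

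Counts of the shared tags were scaled with TMM factors from edgeR 4.0.16 in R 4.3.3, which ranged from 0.717 in the salt control to 1.33 under sucrose. Levels are given as CPM (reads scaled to a common library size), and log2 ratios used a prior count of 1 read, scaled by library size. Tags with a mean of at least 10 CPM over the 7 libraries were kept, 3361 in all. Each group holds 1 library, so no p-value or standard error was computed for any difference between conditions. The only p-values come from permutation tests that shuffled ratios over tags, and they describe where tags lie within these libraries. Tags at least 2-fold higher or lower were counted, and the same count between the 2 control libraries is the only measure of how far libraries of unstressed cells lie apart. These 2 libraries stand in separate blocks, while each stress was compared within its block, so that count may also hold a difference between blocks. Intervals are 95% exact Poisson intervals for reads and exact conditional binomial intervals for log2 ratios. They cover counting error only, not the spread between cultures, and reads were not stated to carry molecular identifiers. Libraries differed far beyond sampling noise, with no pair alike enough to be 1 library deposited again.

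Before the data were examined, the rule for naming was fixed. It ranked the 12 highest and 12 lowest ratios per comparison among tags that were also at least 2-fold away, in the same direction, from the other 0 h control. With no gene names, the rule allowed 2 tags per direction to be named. In the comparison of the controls there is no other control, and the ranking alone applied. The comparisons, the fold thresholds and the alternatives were fixed at the same time. The alternatives were prior counts of 0.1 and 10, no filter or a filter of 50 CPM, size factors from DESeq2 1.42.0, upper-quartile scaling, and the other control or the mean of both. Plain library totals, thinning to the smallest library, the tags of each block alone, a counting interval wholly past 2-fold and the search for series of consecutive tag numbers were added after seeing the data. Overlaps between responses that share a control were set beside 100 simulated sets of unchanged libraries, whose noise was drawn from the difference between the 2 controls. The other calculations ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

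The ratio calculation was tested on simulated data. For each of the 6 pairs of libraries, reads were drawn from the control's levels with 200 tags changed by a log2 ratio of 2 or 3. In every pair, 100% of the changed tags above the filter came out past 2-fold at either size, and 0 unchanged tags did. Between 2993 and 3161 tags stood above the filter in a simulated pair. There the filter took the mean within the pair, not over the 7 libraries, so tags with few reads in both libraries were left out. These draws hold counting error only and no spread between cultures. All planted changes lay well past 2-fold, so recovery near that threshold was not tested.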

Results

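The response of Halothece sp. PCC 7418, a cyanobacterium that grows in strongly saline water, was measured by RNA sequencing after 5 abiotic stresses. Cells grown in medium with 0.5 M NaCl were moved for 24 h to 2.0 M NaCl, to 1.0 M sucrose on top of 0.5 M NaCl, or to medium without a source of sulfur (S), phosphorus (P) or nitrogen (N). The series' title names the synthesis of glycine betaine, a compatible solute, and mycosporine-2-glycine, a UV-absorbing compound, as its subject. The table gives locus tags without gene names, so the genes of these pathways are not reported here, and results are given by tag and by groups of tags. Each condition had 1 library and no difference has a replicate check. Each stress was also compared with a culture at 0 h, so that time and transfer to fresh medium changed together with the stress.

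The libraries held between 13643088 and 18421301 counted reads. Reads on tags shared by all libraries ranged from 9481836 under S starvation to 16045659 under P starvation, with a median of 707 to 1362 reads per tag above the filter. The 10 most abundant tags took 27.6% of these reads in the salt control and 23.0% in the starvation and sucrose control. They took 21.0% after salt upshock, 23.3% under N starvation, 17.7% under P starvation, 18.4% under S starvation and 11.1% under sucrose. The most abundant tag of the salt control took 8.65% of its reads and 4.56% of those of the other control, against 0.059% under sucrose. Across tags, and among the 21 pairs of libraries, the P- and S-starved libraries were the most alike pair (Pearson r = 0.93, Spearman rho = 0.92 of log2 CPM), and the N-starved and sucrose libraries the least alike by Pearson r (r = 0.61, rho = 0.64). The sucrose library was closest to the salt upshock library (r = 0.79, rho = 0.80, 1299 tags at least 2-fold apart), while the salt upshock library was closest to the P-starved one (r = 0.85, rho = 0.85, 802 tags). Tags are not independent replicates, and these correlations describe the libraries only.

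The 2 control libraries, both from 0 h cultures in 0.5 M NaCl medium, show how far apart 2 libraries of unstressed cells lay in this series. They stand in separate blocks of the table, while each stress was compared within its own block. Their difference may therefore hold a difference between blocks that the counts for the stresses do not. In the starvation and sucrose control, 319 of the 3361 tags were at least 2-fold higher and 333 at least 2-fold lower than in the salt control, 19.4% in all. Of these, 64 and 96 were past 4-fold. PCC7418_1122 was highest, with 689 reads (95% interval 639 to 742) against 13 (6.92 to 22.2), a log2 ratio of 5.52 (4.81 to 6.51). PCC7418_1120 followed at 5.39 (5.16 to 5.64). PCC7418_1893 was lowest, with 13 reads against 4153, a log2 ratio of -8.37 (-9.36 to -7.67), and PCC7418_1895 stood at -7.90 (-9.24 to -7.05). Of the 12 lowest tags, 10 carried a number next to that of another of the 12. Their median level was 397 CPM in the salt control, 48.0 CPM under N starvation, 22.9 CPM after salt upshock and at most 5.39 CPM in the other 4 libraries. With upper-quartile scaling the split was 406 higher and 266 lower, and with plain library totals 536 and 212.

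**Figure D1:**
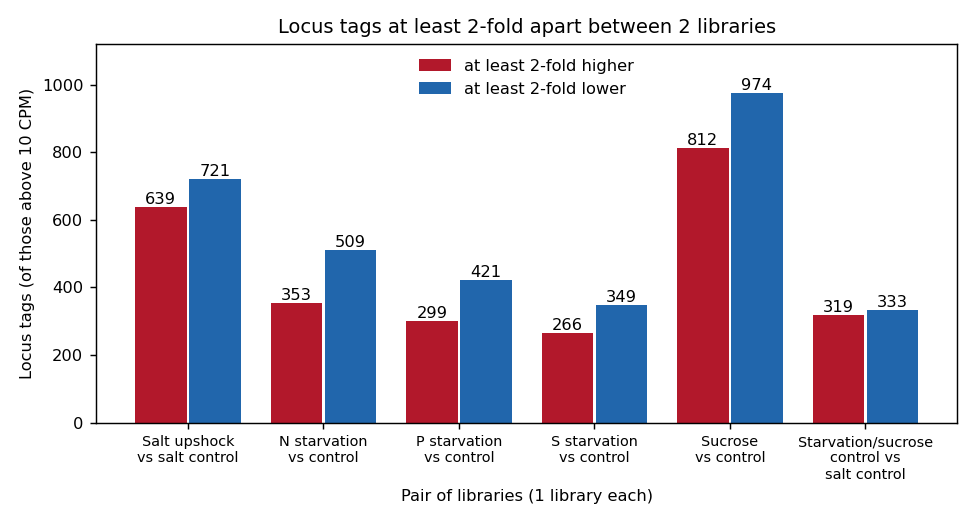
Number of locus tags (y axis) at least 2-fold higher (red) or lower (blue) in each pair of libraries (x axis), 1 library each, among the 3361 tags above 10 CPM. The 2 control libraries differed at 319 and 333 tags, close to the 266 and 349 of S starvation, and sucrose gave the highest bars, 812 and 974.

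Salt upshock asked how cells respond to a rise from 0.5 M to 2.0 M NaCl. After 24 h, 639 tags were at least 2-fold higher and 721 at least 2-fold lower than in the salt control, 40.5% of the tags, and 171 and 310 of them were past 4-fold. PCC7418_2570 was the highest, with 2806 reads (2703 to 2912) against 20 (12.2 to 30.9), a log2 ratio of 6.52 (5.94 to 7.29), and of 5.30 against the other control. It stood at 61.6 CPM under N starvation and 42.1 CPM under S starvation, and at no more than 6.11 CPM in the other 4 libraries. PCC7418_1467 stood at 468 CPM against 6.65 CPM, a log2 ratio of 6.12 (5.78 to 6.52), but its level in the other control was 160 CPM, which leaves a log2 ratio of 1.55. PCC7418_1472, one of the most abundant tags of both controls, was the lowest, at 225 CPM against 20266 CPM, a log2 ratio of -6.50 (-6.55 to -6.45). It was below both controls in every other 24 h library too. There it stood at 993 CPM under N, 1684 CPM under P and 2632 CPM under S starvation, and at 1766 CPM under sucrose. PCC7418_0369 stood at 33.3 CPM against 1680 CPM, a log2 ratio of -5.65 (-5.79 to -5.52), and of -4.59 against the other control. It too was below both controls in every 24 h library, at 35.1 CPM under sucrose and at 140 to 319 CPM in the starved libraries. The 12 highest tags had a median of 341 CPM against 8.81 CPM, but 67.3 CPM in the other control and 478 CPM under N starvation. The 12 lowest had 32.5 CPM against 1507 CPM, and 458 CPM in the other control.

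The salt difference between libraries was larger than that between the controls, at 1360 against 652 tags. Against the other control, 388 of the 639 higher and 481 of the 721 lower tags stayed past 2-fold in the same direction, while 14 and 40 were past 2-fold in the opposite one. With upper-quartile scaling the split was 815 higher and 591 lower, and with plain library totals 1144 and 453.

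Nitrogen starvation, by leaving out nitrate, gave the steepest single differences of the series. At 24 h, 353 tags were at least 2-fold higher and 509 at least 2-fold lower than in the control. PCC7418_1781 had 22371 reads (22079 to 22666) against 4 (1.09 to 10.2), a log2 ratio of 11.93 with a counting interval from 10.83 to 14.06. PCC7418_1782 had 4951 reads against 5, a log2 ratio of 9.48 (8.47 to 11.31). PCC7418_1781 stood at no more than 10.1 CPM in any other library and PCC7418_1782 at no more than 4.84 CPM, both under sucrose. The 12 highest tags ranged from a log2 ratio of 6.57 to 11.93 and had a median of 534 CPM under N starvation against 1.83 CPM in the control, and 11 of them carried a number next to that of another. PCC7418_0363 was the lowest, at 10.9 CPM against 476 CPM, a log2 ratio of -5.44 (-5.71 to -5.21), and of -8.41 against the other control. It was below both controls in the other 24 h libraries too, at 102 to 239 CPM. PCC7418_3602 had 6 reads against 192, a log2 ratio of -5.06 (-6.73 to -4.11), and of -2.84 against the other control. None of the 12 lowest tags had a neighbour by number among the 12.

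The N starvation count of 862 tags stood above the 652 between the controls, and was 1228 against the other control. Against the other control, 240 of the 353 higher tags and 357 of the 509 lower tags stayed past 2-fold, and 50 and 0 were past 2-fold in the opposite direction.

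Phosphorus starvation gave few large increases. Of the tags, 299 were at least 2-fold higher and 421 at least 2-fold lower than in the control, with 20 and 76 past 4-fold (64 and 96 between the controls). PCC7418_2479 was the highest, with 8330 reads (8152 to 8511) against 119 (98.6 to 142), a log2 ratio of 5.30 (5.05 to 5.58), and of 3.94 against the other control. PCC7418_2478, the tag before it by number, had 640 reads against 23, a log2 ratio of 3.93 (3.38 to 4.64). PCC7418_2479 also stood at 372 CPM after salt upshock and 333 CPM under S starvation, against 3.46 CPM under N starvation. PCC7418_0183 was the lowest, at 13.2 CPM against 352 CPM, a log2 ratio of -4.73 (-4.93 to -4.55), followed, among tags also lower than in the other control, by PCC7418_3488 at 4.64 CPM against 91.7 CPM and a log2 ratio of -4.28 (-4.64 to -3.98). Both were below both controls in every 24 h library, PCC7418_0183 at no more than 75.5 CPM and PCC7418_3488 at no more than 12.4 CPM. The total of 720 tags stood beside 652 between the controls, and was 1110 against the other control and 841 against the mean of both. Against the other control, 206 of the higher and 245 of the lower tags stayed past 2-fold, and with plain library totals the split was 662 higher and 217 lower.

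Sulfur starvation gave the smallest count of the 5 stresses. It had 266 tags at least 2-fold higher and 349 at least 2-fold lower, a total of 615 beside the 652 between the controls. The order of these totals turned with a filter of 50 CPM (440 and 413) and with plain library totals (834 and 748), and S starvation gave 1014 tags against the other control and 711 against the mean of both. PCC7418_2546 was the highest, with 1049 reads (986 to 1114) against 26 (17.0 to 38.1), a log2 ratio of 5.25 (4.73 to 5.91), and of 3.10 against the other control. Its level was 98.4 CPM under S starvation and 211 CPM under N starvation, and at most 13.6 CPM elsewhere. PCC7418_2479, the highest tag of P starvation, was second at a log2 ratio of 4.85 (4.59 to 5.13), and 3.49 against the other control. PCC7418_2449, an abundant tag of both controls, was the lowest, at 98.0 CPM against 6257 CPM, a log2 ratio of -6.00 (-6.09 to -5.91). It stood at no more than 547 CPM in any 24 h library, and at 5365 CPM in the salt control. PCC7418_0183, the lowest tag of P starvation, followed at -5.77 (-6.15 to -5.44). Past 4-fold were 30 higher and 99 lower tags, beside 64 and 96 between the controls. Against the other control, 155 of the tags 2-fold higher and 231 of the tags 2-fold lower stayed past 2-fold. With upper-quartile scaling the split was 357 higher and 310 lower, with plain library totals 624 and 210, and requiring the counting interval to lie wholly past 2-fold left 167 higher tags.

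**Figure D2:**
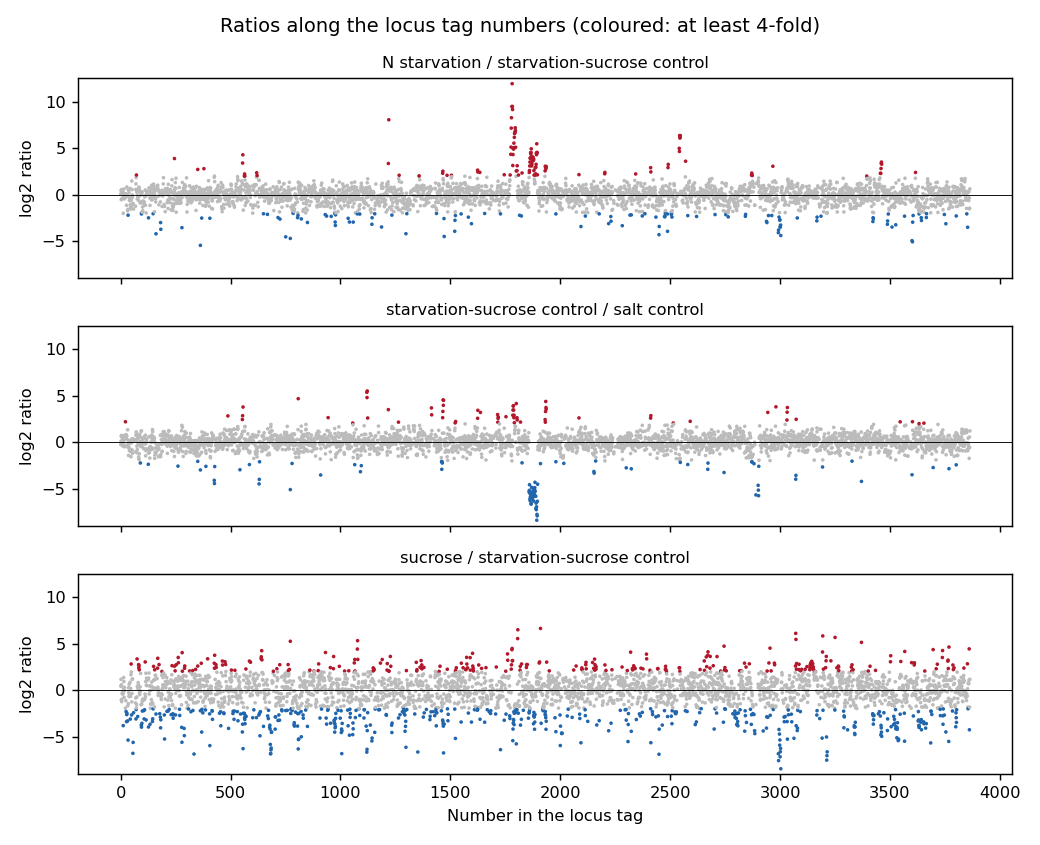
Log2 ratio of each tag (y axis) by the number in the locus tag (x axis) for N starvation, for the 2 controls and for sucrose, 1 point per tag, red at least 4-fold higher and blue at least 4-fold lower. The tags around PCC7418_1781 reach a log2 ratio of 11.93 under N starvation, and those around PCC7418_1893 reach -8.37 between the controls.

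Sucrose, which raises the osmotic strength of the medium without added salt, changed the most tags. At 24 h, 812 tags were at least 2-fold higher and 974 at least 2-fold lower than in the control, 53.1% of the tags, with 280 and 507 past 4-fold. PCC7418_1910 was the highest, with 19211 reads (18940 to 19485) against 104 (85.0 to 126), a log2 ratio of 6.63 (6.36 to 6.93). PCC7418_1807 followed at 880 CPM against 9.74 CPM, a log2 ratio of 6.49 (6.21 to 6.79). Both were also high after salt upshock, at 542 CPM and 850 CPM, and at no more than 22.6 CPM in any starved library. In the salt control they stood at 49.1 CPM and 23.4 CPM, which leaves log2 ratios of 4.35 and 5.23. PCC7418_3003 was the lowest, with 52 reads (38.8 to 68.2) against 10147, a log2 ratio of -8.46 (-8.92 to -8.11). PCC7418_2993 had 100 reads against 10491, a log2 ratio of -7.58 (-7.90 to -7.32). Both were below both controls in every other 24 h library too, PCC7418_3003 at 46.6 to 197 CPM and PCC7418_2993 at 72.8 to 301 CPM. Against the other control, 629 of the higher and 765 of the lower tags stayed past 2-fold, and with plain library totals the split was 1322 higher and 667 lower.

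**Figure D3:**
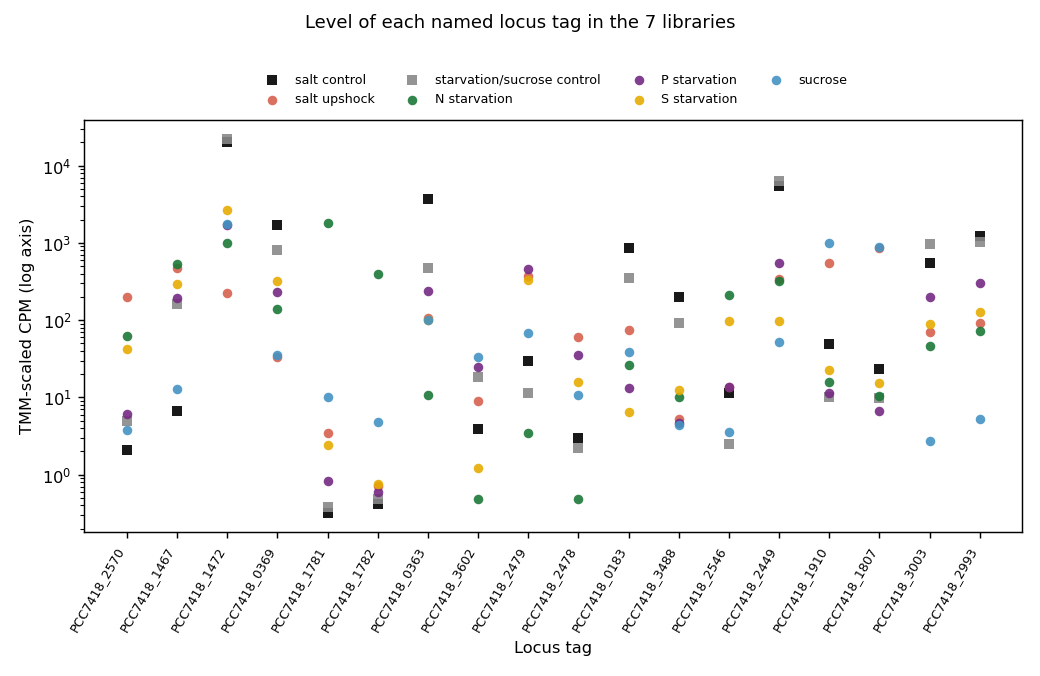
Level of each named locus tag (x axis) in the 7 libraries, as TMM-scaled CPM on a log axis (y axis); squares are the 0 h controls and circles the 24 h libraries, 1 point per library and no error bars. PCC7418_1781 stands at 1799 CPM under N starvation and at no more than 10.1 CPM elsewhere, and PCC7418_1910 and PCC7418_1807 are highest under sucrose and salt upshock.

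Salt upshock and sucrose both raise the external osmotic strength, and each had a control of its own. The 2 responses were correlated across tags (Pearson r = 0.47, Spearman rho = 0.49, 3361 tags, which are not independent replicates). At least 2-fold higher in both were 307 tags, against 154 for independent lists of these sizes, and 455 were lower in both, against 209. The 307 stood among 639 higher tags for salt and 812 for sucrose, and the 455 among 721 and 974 lower tags. In opposite directions, 92 tags were higher after salt and lower under sucrose, and 34 the reverse, against 185 and 174 for independent lists. With the 2 controls exchanged, r was 0.46 and the shared tags numbered 297 and 478. Both ratios set 24 h against 0 h, and the overlap of salt upshock with each starvation response was not computed. The overlap can therefore not be credited to osmotic strength alone. In log2 CPM levels, which are another measure than responses, the salt upshock library was closer to the P-starved library (r = 0.85) than to the sucrose one (r = 0.79).

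**Figure D4:**
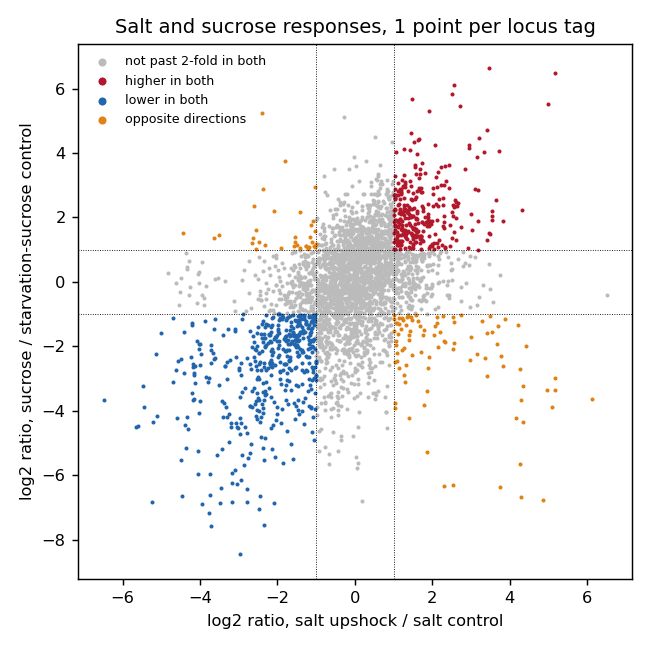
Log2 ratio of each of the 3361 locus tags after salt upshock against the salt control (x axis) and under sucrose against the starvation and sucrose control (y axis), 1 point per tag, with dotted lines at 2-fold. The 307 tags higher in both (red) and the 455 lower in both (blue) outnumber the 92 and 34 in opposite directions (orange).

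The starvation and sucrose responses share 1 control library. All 4 were at least 2-fold higher at 14 tags and at least 2-fold lower at 124, but at 92 and 261 against the other control and at 65 and 66 with plain library totals. Simulated unchanged libraries against 1 such control gave a mean of 77.4 and 79.1 tags (at most 104 and 99 in 100 sets), while independent lists would give 0.6 and 1.92. Against both controls at once, 4 tags were higher and 82 lower in all 4 libraries. Among the 4, PCC7418_3407 had log2 ratios of 1.23 to 1.71 against the starvation and sucrose control, and PCC7418_0150 stood at 2.71 under S starvation, 2.55 under sucrose and 1.36 under P starvation, but at no more than 29.4 CPM in any of the 7 libraries. Ranked by the smallest of their 4 differences, the first of the 82 were PCC7418_0279, with log2 ratios of -5.61 to -3.54, and PCC7418_2449, with -6.90 to -3.52. Of the 124 tags, 88 were also at least 2-fold lower after salt upshock. P and S starvation had the highest correlation among these responses (r = 0.64), with a covariance of 0.507 against 0.615 simulated from the shared control alone. The covariance was 0.38 for N and P and 0.554 for N and S starvation, and above the simulated value only in the pairs with sucrose, at 0.723 with N, 0.87 with P and 0.769 with S starvation. The noise was scaled so that simulated ratios spread about as widely as the 2 controls differ (standard deviation of log2 ratios 1.11). That is wider than the P (0.88) and S (0.907) starvation responses themselves, and narrower than those of N starvation (1.22) and sucrose (1.84). The simulated values therefore cannot show how much of an overlap comes from the shared control, and part of any overlap may come from it.

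A direct comparison of the 3 starved libraries asked which tags set 1 nutrient apart, by at least 4-fold from the control and from both other starved libraries. N starvation had 67 such tags higher and 13 lower, P starvation 4 and 15, and S starvation 5 and 7. Sucrose and salt upshock were not part of this comparison. Of the lower tags, 7 of the 13 of N starvation, all 15 of P starvation and 5 of the 7 of S starvation were also at least 2-fold lower under sucrose, and 11, 3 and 3 of them after salt upshock. Of the higher tags, 10 of the 67, 1 of the 4 and 3 of the 5 were also at least 2-fold higher under sucrose, and 7, 3 and 1 after salt upshock. Of the 67, 58 carried a number next to that of another, and 39 were also at least 4-fold above the other control. PCC7418_1781 and PCC7418_1782 had the widest gaps among them. The lower ones were led by PCC7418_0772, at 2.01 CPM under N starvation against 309 CPM and 112 CPM under P and S starvation, and PCC7418_0161, at 51.9 CPM against 828 CPM and 1209 CPM, the latter also low after salt upshock (135 CPM) and under sucrose (161 CPM). For P starvation, PCC7418_0041 stood at 455 CPM against 62.5 CPM in the control (log2 ratio 2.86, 2.75 to 2.98), 40.6 CPM under N and 77.4 CPM under S starvation. PCC7418_3485 stood at 170 CPM against 21.5 CPM (2.98, 2.79 to 3.19). PCC7418_0808 and PCC7418_1800 had the widest gaps among the lower tags, at 7.53 CPM and 5.18 CPM against 106 CPM and 121 CPM, but their levels in the salt control were 4.01 CPM and 6.65 CPM, and only 1 of the 15 lower tags was also 4-fold below that control. For S starvation, PCC7418_0149 stood at 3515 CPM against 273 CPM (3.68, 3.63 to 3.74), with at most 577 CPM in any other library. PCC7418_3084 stood at 790 CPM against 73.2 CPM (3.43, 3.32 to 3.54). PCC7418_0557 and PCC7418_2412 had the widest gaps among the lower tags, at 117 CPM and 57.3 CPM against 2600 CPM and 424 CPM. In the salt control they stood at 186 CPM and 57.6 CPM, less than 2-fold from their levels under S starvation, and 4 of the 7 lower tags were also at least 4-fold below that control. All 5 higher tags of S starvation and 3 of the 4 of P starvation were also at least 4-fold above the other control.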

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

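The counts with plain library totals and with thinned reads were added after the data were seen, and the other tests of this part were chosen first. Each stress has 1 library, so none of the differences between stresses given here was tested.

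The 2 control libraries differed by at least 2-fold at 652 tags, beside 615 for S starvation (413 and 440 with a filter of 50 CPM, 748 and 834 with plain library totals), which gave 1014 against the other control and 711 against the mean of both. Counting error alone gave 0 such tags in the simulated pair. That pair kept 2993 tags by their mean within the pair, so tags with few reads in both controls were not covered. Among the 3361 tags, 216 higher and 253 lower ones had a counting interval wholly past 2-fold. Other scalings gave 645 to 748, so none of the scalings tried removed the difference. Different counting of the 2 blocks of the table would shift the salt upshock library in the same way as the salt control, but over these tags it lay off the N-, P- and S-starved libraries by a median of 0.319 times the control difference (0.45 against 1.41 on the log2 scale, the same way in 69.3% of tags), which argues against it as the whole cause. That shift also holds the responses to salt and starvation, which weakens the check, and a part played by counting stays open. A batch shared by the 2 salt libraries would give the same shift as different counting, so the test cannot tell the 2 apart. The state of the cultures at 0 h and a batch of growth or sequencing also stay open, since the labels name no batch and the controls stand in separate blocks.

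Sucrose changed 1786 tags, more than any other stress. Thinning every library to the smallest gave 1788, which argues against depth. Over the scalings, the sucrose count was at least 1.2 times the next largest, and against the salt control it was 1756, so neither scaling nor its own control accounts for it. RNA quality, cell death and a single deviating culture remain open, because 1 library cannot show them and no test here bears on them.

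Salt and sucrose moved 92 tags apart with salt higher and 34 with salt lower, each against its own control, and 81 and 25 of them were also at least 2-fold apart in that direction between the 2 stressed libraries. Among named tags the difference of log2 ratios, salt minus sucrose, was 9.74 for PCC7418_1467 (6.12 and -3.62), 9.93 for PCC7418_2412 (4.27 and -5.66), 8.83 for PCC7418_0557 (2.53 and -6.30), 8.62 for PCC7418_0808 (2.29 and -6.33), -7.65 for PCC7418_0772 (-2.40 and 5.24) and -4.17 for PCC7418_3084 (-2.56 and 1.61). These differences include the difference between the 2 controls. Between the stressed libraries themselves the log2 ratio was 5.17 for PCC7418_1467, 7.05 for PCC7418_2412, 5.02 for PCC7418_0557, 3.92 for PCC7418_0808, -2.57 for PCC7418_0772 and -4.30 for PCC7418_3084. N and P starvation moved 42 tags apart with N higher and 11 with N lower, against 44.2 and 45.3 for independent lists, which take no account of the shared control. The difference, N minus P, was -7.01 for PCC7418_2479, -5.97 for PCC7418_2478, -7.21 for PCC7418_0772, 5.15 for PCC7418_0808 and 7.08 for PCC7418_1800. N and S starvation moved 8 tags apart with N higher and 13 with N lower, against 36.7 and 40.3 for independent lists. The difference, N minus S, was -6.56 for PCC7418_2479, -4.86 for PCC7418_2478, -5.75 for PCC7418_0772, 3.55 for PCC7418_1800, -5.09 for PCC7418_3084 and 5.34 for PCC7418_2412. P and S starvation moved 4 tags apart with P higher and 12 with P lower, against 31.0 and 33.3 for independent lists. In the differences between starved libraries the shared control cancels.

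Rows and tags outside the comparisons also carried signal. The largest row without a tag took 30.8% of all reads under S starvation (95% exact interval 30.8 to 30.8), against 13.8% in its control and 6.94% under sucrose. Among the 27 untagged rows with a mean of at least 10 CPM, 3 were at least 2-fold above the control and 10 below it under N starvation, 0 and 7 under P starvation, 2 and 4 under S starvation, and 5 and 18 under sucrose. Of the 50 tags listed in the salt block alone at that level, 7 were at least 2-fold higher after salt upshock and 24 lower.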

How the results depend on the processing

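Plain library totals, the counting interval, thinning and the tags of each block alone were added after the data were seen. The balance of higher and lower tags turned from mostly lower to mostly higher with plain library totals for salt, P and S starvation, sucrose and the controls, and with upper-quartile scaling for salt (815 and 591), S starvation (357 and 310) and the controls (406 and 266). The correlation of salt and sucrose kept its sign. A change of scaling shifts all ratios of a pair nearly alike and could not alter it, so its values under other scalings are no check. Of the alternative values, those correlations included, 208 lay within 1.5 times the reported count or inside the interval of the reported correlation, and 35 did not. No paired analysis was possible because each group holds 1 library. For the 24 ratios of named tags (PCC7418_2479 and PCC7418_0183 each under 2 stresses), 174 alternative values lay inside the counting interval and 52 outside it. The 24 values with no filter and the 18 with a filter of 50 CPM could not move, since a filter leaves a tag's ratio as it is. Against the other control 16 of 20 values lay outside the interval, and against the mean of both controls 16 of 20. The sign of the ratios was not tested by the alternatives. The naming rule asked for the same direction against the other control, and the ratios are far larger than any shift of scaling. With a filter of 50 CPM fewer tags (2234) were tested, and the tags 2-fold higher numbered 419 after salt upshock, 235 under N starvation, 165 under S starvation and 186 between the controls, with 198 higher in both salt and sucrose, 4 higher in all 4 responses sharing a control, and 39 specific to N starvation; with no filter, 22 were higher in all 4. Against the other 0 h control, the higher tags numbered 530 under N, 520 under P and 473 under S starvation, the lower tags under S starvation 541, and those in all 4 responses 92 and 261; the tags specific to one nutrient numbered 41 for N higher, 3 for P lower and 4 for S lower, and with the mean of both controls 41 for N higher and 7 for P lower. With a counting interval wholly past 2-fold, 167 tags were higher under S starvation. Plain library totals moved the median of all tags by 0.53 after salt, 0.39 under P, 0.37 under S starvation, 0.61 under sucrose and 0.28 between the controls, and gave 1144 higher and 453 lower after salt, 662 and 217 under P, 624 and 210 under S starvation, 1322 higher under sucrose and 536 and 212 between the controls. With them 692 and 274 tags were shared by salt and sucrose, 65 and 66 by all 4 responses, and 10 and 4 were specific to S starvation. Upper-quartile scaling moved the median by 0.21 after salt, 0.12 under S starvation and 0.13 between the controls. Depth limits mainly ratios with few control reads, such as PCC7418_1781 with 4, since the median tag had at least 707 reads. The cause of the shifts with the control was not tested.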

Other observations

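The description of tags by consecutive numbers, and the tests of random placement and control state, were chosen after the data were seen; the test of read depth was written down first. An earlier form of the control-state test split the tags by how the controls differ, which all but fixed its outcome, and it was replaced by a search against the other control. Tag numbers are taken here as the order of genes, which the file does not state.

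Some of the large differences fell on stretches of consecutive tag numbers. Under N starvation, 64 of the 118 tags at least 4-fold higher lay in 6 series of at least 5 consecutive numbers. The steepest was a series of 18 tags that holds PCC7418_1781 and PCC7418_1782, with a median log2 ratio of 6.37 against its own control and 8.24 against the salt control. The 6 tags ending at PCC7418_2546 were higher under both N starvation (median log2 ratio 6.12) and S starvation (4.60). Under sucrose, a series of 18 tags stood at a median of 480 CPM against 73.7 CPM in the control, 212 CPM under P starvation and 108 CPM after salt upshock, while 97 of the 496 lower tags with a plain number lay in 15 series, among them 7 tags with PCC7418_3003 at a median log2 ratio of -6.26. Of the 15 series, 3 with 19 tags in all had median log2 ratios of -0.02, -0.09 and 0.04 against the other control. After salt upshock 71 of the 310 lower tags lay in 7 series, and 12 of the 171 higher ones lay in 2, whose medians of 5.09 and 4.17 were 1.55 and 1.01 against the other control. Most tags past 4-fold lay outside such series in every direction but the higher tags of N starvation; of the 124 lower tags under N starvation, 6 lay in a series, and of the 20 higher tags under P starvation 0 did.

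A further stretch stood higher in the salt control than in the other 6 libraries. Series of 19 tags (PCC7418_1858 to PCC7418_1876) and 20 tags (PCC7418_1878 to PCC7418_1897) were lower in the starvation and sucrose control, with median log2 ratios of -5.81 and -5.79. The longer holds PCC7418_1893 and PCC7418_1895. The series of 20 had a median of 354 CPM in the salt control, 34.9 CPM under N starvation, 23.7 CPM after salt upshock and at most 7.64 CPM in the other 4 libraries. The same stretch supplied 39 of the 71 lower tags in series after salt upshock, and against the other control these 2 series were higher after salt upshock, by a median of 1.42 and 1.79.

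A candidate explanation for the N starvation series is that neighbouring genes are switched on together, and a one-sided permutation test that shuffled the ratios over the tags 10000 times gave at most 0 tags in such series against 64 observed (p = 0.0001, the smallest it can give), which argues against random placement. The same holds in 11 of the 12 directions examined, both directions between the unstressed controls among them, so it is no mark of N starvation. Few reads in the control do not account for the series either, since 93.8% of the 64 tags had a counting interval wholly above 4-fold. Searched anew against the salt control, 41 tags lay in such series (at most 6 in 10000 shuffles), 35 of them among the 64. Exceeding the shuffles is no check on the control, since 11 of the 12 directions did so. The 35 tags were at least 4-fold above both controls, which argues against the state of the control as the whole cause. For the other 29 tags, of which 0 were at least 4-fold above the salt control and 16 were at least 4-fold below it, the state of the cultures stays open, although 25 of them were at least 4-fold above both the P- and the S-starved library. The N starvation series of 18 and 11 tags within the stretch that stood higher in the salt control had median log2 ratios of -1.90 and -3.26 against it.

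All shared tags whose number begins with R, above the filter or not, took between 0.815% of the reads on shared tags under N starvation and 4.55% under S starvation. Of the 30 above the filter, the numbers at least 2-fold higher and lower were 3 and 18 under sucrose, 2 and 9 under N starvation, 7 and 1 under P starvation, 11 and 0 under S starvation, 3 and 6 after salt upshock, and 1 and 9 between the controls. The file does not say what these tags are.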
